A study of Gallus gallus with 13 samples.

How the data were processed

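The 13 samples were FLAG chromatin immunoprecipitations of HOXD13 wt, Q317K, Q317R and PITX1, 1 input for each, and 5 RNA libraries from cultures infected with the same viruses or with the empty vector. Reads were 36 bp long for chromatin and 115 bp for RNA, per the labels' protocols, and the mRNA was selected on oligo-dT. Groups were taken from the sample titles. The series design speaks of 2 biological replicates for each immunoprecipitation, but each factor has 1 peak list, and whether it pools replicates is not given in the sources used here. Input files were not analysed here.

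Peaks were called with MACS2, per the submitters' processing notes. The deposited peak lists give for each peak its position, a score, a fold enrichment ratio, a −log10 p-value and the offset of the summit, and the q-value column holds −1 in every row. Aligner, genome build, input handling and thresholds are not given in the sources used here. Peak names are numbered up to 323528 for HOXD13 wt, 319685 for Q317K, 350075 for Q317R and 301605 for PITX1, so the lists hold 10.6%, 7.83%, 6.11% and 13.6% of the numbers used. The lists' largest position on chromosome 1, 200839888, lies beyond the last gene of the GRCg7b annotation given for names, at 196443699, so positions from that annotation were not combined with the peaks.

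RNA values were deposited as RPKM for 21998 Ensembl transcripts, per the file headers; the counting tool and annotation release are not given in the sources used here. Because RPKM is reads divided by transcript length and library total, whole read numbers, lengths and totals were worked out from ratios between columns. All 21998 rows, or 100%, came out whole within a tolerance of 0.001. In 3000 simulated rows the true reads and lengths came back in 98.6%; in other rows both can be too small by a common factor, which widens counting intervals and leaves RPKM as it was. The rows summed to 92.5% to 94.9% of the totals. Each of 16737 Ensembl genes was represented by its longest transcript, and 9271 of them had a printable name. For 96 entries labelled by a UniProt name the gene symbol was written by hand, such as ACAN for the chicken aggrecan entry; CYT, MYSC, K2CO and HSP25 are printed as labelled. Some of these translations were added after the genes of largest ratio had been seen, and they brought ALPL into the hypertrophic cartilage and bone list, so its counts and medians with ALPL are not independent of the data.

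RNA libraries were compared as log2 of the ratio of RPKM + 1, among genes with an RPKM of at least 5 in 1 or both libraries, and genes at least 2-fold apart were counted. Ratios on this scale understate differences of low genes. Fold ratios in the text are of RPKM without the pseudocount, with 95% exact (Clopper-Pearson) intervals on the recovered reads; reads are not independent molecules, so the intervals cover counting error only. No p-values were computed between conditions. Genes named in the text were those carried by the viruses, the 8 with the largest positive and the 8 with the largest negative log2 ratio among named genes, and up to 4 members of each of 18 gene lists. This rule, the lists, the groups, the comparisons and most other settings tried were fixed before the data were examined. Genes named outside the rule, such as levels given for a second library, were chosen after their values were seen, and a few genes that the rule names are not reported here. Also chosen after the data were seen were the shares among the 1000 strongest peaks, the merged regions and the split of peaks by the lists they overlapped. List members with an RPKM of at least 5 in any library counted as measured, and each list's median was placed among 10000 random lists of the same size matched in 20 bins of mean expression, as a description of these libraries; 18 lists in 7 comparisons were placed in this way.

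Peak lists were compared by overlap of at least 1 bp, with 95% exact binomial intervals over peaks and the mean of 100 random placements on the same chromosomes, each taken to end at its largest peak position. Correlations across genes used libraries without a shared control, with 1000 resamplings of genes. For ratios that share the empty vector, 20 Poisson simulations of unchanged groups gave the values from counting noise alone. Steps were tested on simulated data: in the comparison of HOXD13 wt with the empty vector, over 12432 genes, all 50 genes raised 3-fold were found, none of 50 raised 1.5-fold was, and 3 unchanged genes were called from counting noise. Of 50 genes lowered to 0.2 of their level, 46 were found in Q317K, 49 in PITX1 and all in the others. With Q317K 6 unchanged genes were called, and with PITX1 1 of 50 raised 1.5-fold was. Overlap counts equalled those of bedtools 2.31.1. Of 200 unshifted simulated lists, 7.00% lay outside the central 95% of random lists, and of 200 lists shifted by a log2 ratio of 0.5, 96.0% lay above it. Scripts used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

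Alternatives were another pseudocount (0.1), a filter at RPKM 1 or 20, ratios centred on their median, another transcript per gene, other overlap rules, stricter or equal-length peak lists, rank correlation and a correlation without HOX and PITX rows. Sites for homeodomain motifs at summits and the expression of genes near peaks, 12 planned results with 28 alternatives, were left out because no genome or gene positions of the peaks' build were at hand.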

Results

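Mesenchymal cells from chicken limb buds at Hamburger-Hamilton stage 24 were infected with avian retroviruses and grown for 9 days as micromass cultures, dense droplets in which limb mesenchyme forms cartilage. The viruses carried FLAG-tagged mouse HOXD13, the HOX factor of the distal limb, as wild type (wt) or with a glutamine of the homeodomain replaced by lysine (Q317K) or by arginine (Q317R). Other cultures received a virus with PITX1, a homeodomain factor of the hindlimb, or an empty vector. The 13 samples were 4 FLAG chromatin immunoprecipitations, their 4 inputs and 5 RNA libraries. Each factor had 1 peak list and each RNA group 1 library, so there were no replicates to test against; differences are described as higher or lower in these libraries. Intervals in brackets are 95% and cover counting error only. The library totals behind the RPKM values were 14931544 reads for HOXD13 wt, 14069766 for Q317K, 16793118 for Q317R, 16114218 for PITX1 and 15274704 for the empty vector.

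The first comparison asked how far binding of each HOXD13 form coincided with binding of PITX1. Q317K peaks met PITX1 peaks more often than wild-type peaks did: 3944 of 25036 Q317K peaks, or 15.8% (15.3 to 16.2), overlapped a PITX1 peak by at least 1 bp, against 2445 of 34267 HOXD13 wt peaks, or 7.14% (6.86 to 7.41). Q317R lay between them with 2507 of 21396 peaks, or 11.7% (11.3 to 12.2). Random placement of the peaks on the same chromosomes gave mean shares of 6.07% for Q317K, 5.93% for HOXD13 wt and 6.29% for Q317R. The observed share was therefore 2.60 times the random one for Q317K, 1.86 times for Q317R and 1.20 times for HOXD13 wt. Placement was uniform along each chromosome and took no account of open chromatin. A ratio above 1 therefore does not by itself show a shared choice of sites. Among the 1000 Q317K peaks with the largest fold, 21.0% (18.5 to 23.7) overlapped PITX1, and among the 1000 strongest HOXD13 wt peaks 5.40% (4.08 to 6.99) did so. The PITX1 list was the longest, with 40881 peaks of median width 755 bp. Peaks of HOXD13 wt were 591 bp wide at the median, those of Q317K 624 bp and those of Q317R 668 bp. Median folds, which are the authors' own value for each peak, were 8.06 for HOXD13 wt, 8.24 for Q317K, 7.54 for Q317R and 9.72 for PITX1. The lists ended at different −log10 p, 52.1 for HOXD13 wt, 39.4 for Q317K, 36.7 for Q317R and 42.2 for PITX1, so their lengths do not measure how many sites each factor bound. With summits required to lie within 100 bp of each other, the shares were 6.62% for Q317K, 2.94% for Q317R and 1.11% for HOXD13 wt.

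**Figure D1:**
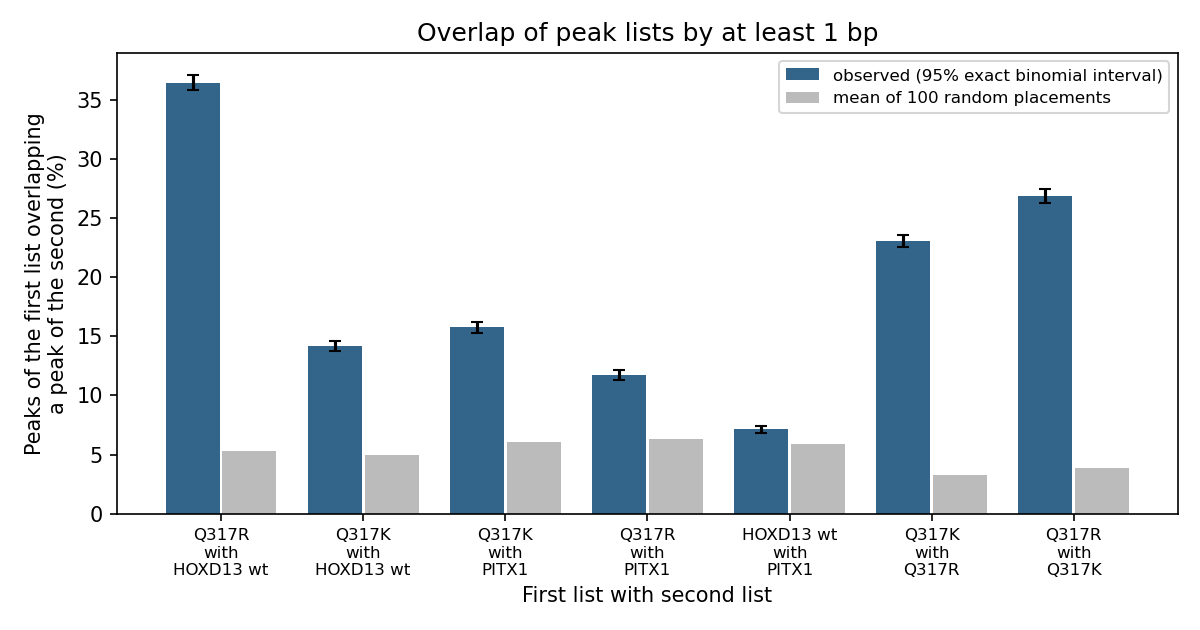
Bars show the percentage of peaks of the first-named list that overlapped a peak of the second by at least 1 bp (blue, with 95% exact binomial intervals) and the mean over 100 random placements of the first list (grey). Q317R with HOXD13 wt is the tallest bar at 36.5%, and HOXD13 wt with PITX1 lies close to its random bar, at 7.14% against 5.93%.

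The mutants were next compared with the wild type. A larger share of Q317R peaks than of Q317K peaks lay on wild-type peaks: 7799 of 21396 Q317R peaks, or 36.5% (35.8 to 37.1), overlapped a HOXD13 wt peak, against 3552 of 25036 Q317K peaks, or 14.2% (13.8 to 14.6). The random means were 5.28% and 4.98%, so the observed shares were 6.90 and 2.85 times the random ones. For Q317K with PITX1, whose list was longer and had wider peaks, the ratio was 2.60. Counted over the wild-type list, 7824 of 34267 HOXD13 wt peaks, or 22.8% (22.4 to 23.3), overlapped a Q317R peak and 3544, or 10.3% (10.02 to 10.7), a Q317K peak, while 72.5% overlapped neither. Among the 1000 strongest peaks, 61.9% (58.8 to 64.9) of Q317R and 22.3% (19.8 to 25.01) of Q317K peaks met a wild-type peak. The mutants also met each other, with 23.1% (22.6 to 23.6) of Q317K peaks overlapping Q317R and 26.9% (26.3 to 27.5) of Q317R peaks overlapping Q317K. Of the Q317K peaks, 3297 overlapped PITX1 but not HOXD13 wt, 2905 overlapped HOXD13 wt but not PITX1, 647 overlapped both and 18187, or 72.6%, overlapped neither. For Q317R the corresponding numbers were 1641, 6933, 866 and 11956, the last being 55.9% of the list. Merging the 4 lists gave 99237 regions, of which 34026 were called for PITX1 alone, 23489 for HOXD13 wt alone, 15024 for Q317K alone and 8855 for Q317R alone. HOXD13 wt and Q317R without the other factors shared 5284 regions, Q317K and Q317R shared 3042, and Q317K and PITX1 shared 2538; 449 regions were called for all 4 factors. A region outside a list can still be bound below that list's threshold.

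The strongest sites by fold differed between the lists. For HOXD13 wt they lay on chromosome 3 from 46687334 to 46687909 (fold 44.3), chromosome 11 from 3858675 to 3859392 (40.8) and chromosome 4 from 7527003 to 7527578 (40.1), the last of which also overlapped a Q317R peak. For Q317K they were chromosome 21 from 4541965 to 4542927 (38.8), which overlapped HOXD13 wt and Q317R peaks, chromosome 1 from 156938300 to 156939909 (38.3), which overlapped peaks of all the other factors, and chromosome 1 from 184586598 to 184587204 (37.0), which overlapped none. Q317R peaked on chromosome 7 from 15134154 to 15135666 (26.3) and chromosome 4 from 61965113 to 61965772 (24.9), both also called for HOXD13 wt, and on chromosome 2 from 27438281 to 27439239 (23.6), called for HOXD13 wt and Q317K as well. PITX1 peaked on chromosome 28 from 3739466 to 3740516 (40.4), shared with Q317K, on chromosome 7 from 603957 to 604924 (40.0), shared with no other list, and on chromosome 4 from 80381737 to 80382561 (39.6), shared with HOXD13 wt. The genome build of these positions is not given in the sources used here, so genes near them were not assigned.

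The PITX1 library carried the gene its label names, and the HOXD13 row was higher in the HOXD13 libraries than in the others. RPKM values cannot show the Q317K and Q317R changes, so the labels of the HOXD13 forms were not checked against each other. PITX1 stood at 6371 RPKM in the PITX1 library and 52.0 in the empty vector, a ratio of 122 (115 to 130), and at 28.3, 30.8 and 22.4 RPKM in HOXD13 wt, Q317K and Q317R. The HOXD13 row was at 63.4 RPKM in HOXD13 wt, 36.8 in Q317K, 53.7 in Q317R, 16.6 in the empty vector and 13.1 in the PITX1 library. The transgene is mouse and the row chicken, so these ratios do not give the dose of the virus. PITX3 was also higher in the PITX1 library than in the empty vector (21.9 against 10.7 RPKM); it resembles PITX1 in sequence, and reads of the transgene could not be told apart from its own.

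Against the empty vector, HOXD13 wt cultures had lower cartilage matrix transcripts and higher COL10A1, the collagen of hypertrophic cartilage. Of 16 measured genes of the cartilage list, 10 were at least 2-fold lower and 1 was higher, with a median log2 ratio of −1.54, below all of 10000 random lists matched on mean expression. EPYC, a cartilage proteoglycan, stood at 5.03 against 77.1 RPKM, 15.3-fold lower (12.8 to 18.5), and the hyaluronan link protein HAPLN1 was 8.61-fold lower (8.18 to 9.07); MATN1 and MATN3, matrilins of cartilage, were 7.31-fold and 8.71-fold lower. COL10A1 stood at 502 against 67.7 RPKM, 7.42-fold higher (7.09 to 7.77). In the hypertrophic cartilage and bone list 4 genes were lower, among them IBSP (9.64 against 34.4), PANX3 (19.3 against 66.0) and the hedgehog ligand IHH (12.5 against 33.8). Low medians were not confined to these lists. Skeletal muscle markers, of another cell type, had a median of −0.42 at percentile 0.16, though none of 15 changed 2-fold. Adipocyte markers had a median of −0.61 at percentile 1.2, with 1 of 4 at least 2-fold lower. Epithelial, endothelial and neuronal markers lay at percentiles 6.59, 58.3 and 27.5. In all, 289 genes were at least 2-fold higher and 334 lower among 12757 with an RPKM of at least 5 in 1 or both libraries.

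CHGB, a granin of secretory granules, had the largest positive ratio in HOXD13 wt, at 359 against 16.8 RPKM or 21.3-fold (19.7 to 23.2). CHRDL2, which binds BMPs, stood at 576 against 62.5 RPKM, and the growth factor BMP6 at 125 against 13.7. ST6GAL2 (59.1 against 4.66), TMTC1 (179 against 19.9), AKR1D1 (258 against 29.5), SCP2 (241 against 28.6) and the protease inhibitor SERPINI1 (48.3 against 5.27) completed the 8 largest positive ratios. C1QTNF3 (18.4 against 237), CYTL1 (45.7 against 460), CLEC3A (8.75 against 89.1), NRIP3 (8.39 against 81.2) and the lysyl oxidase LOXL3 (83.2 against 587) stood with EPYC, HAPLN1 and MATN1 among the 8 most negative. Of 12 measured BMP and TGF-beta genes, BMP4 (60.8 against 14.1), its antagonist NOG (92.1 against 36.7) and TGFB2 (95.8 against 39.7) were at least 2-fold higher, and 2 members, among them TGFB3 (86.1 against 201), were lower, with a list median of 0.06 at percentile 72.0. Of 14 measured WNT genes 1 was at least 2-fold higher, the WNT inhibitor WIF1 (40.6 against 9.70), and 1 lower, DKK3 (39.5 against 80.3), with a list median of 0.44 at percentile 99.97. CYP26B1, which degrades retinoic acid, stood at 78.2 against 24.5 RPKM.

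Q317K cultures had the lowest median of cartilage transcripts among the 4 factor libraries, and higher levels of some bone-type genes. All but 1 of the 16 measured cartilage genes were at least 2-fold lower than in the empty vector, with a median log2 ratio of −2.88, below all 10000 random lists. ACAN, the main cartilage proteoglycan, stood at 59.0 against 940.4 RPKM, 15.9-fold lower (15.5 to 16.4), MATN1 was 13.7-fold lower (12.4 to 15.2), COMP 10.2-fold lower (9.80 to 10.6) and the cartilage collagen COL2A1 8.16-fold lower (8.03 to 8.29). In the hypertrophic cartilage and bone list 4 of 10 genes were higher and 3 lower: IBSP, a mineral-binding bone sialoprotein, stood at 179 against 34.4 RPKM, 5.21-fold higher (4.71 to 5.77), the phosphatase ALPL at 668 against 151 and PANX3 at 238 against 66.0, while COL10A1 was at 14.95 against 67.7 and SPP1, a bone matrix phosphoprotein, at 264 against 573. The list median of 0.40 lay at percentile 97.3, inside the central 95% of random lists. IFITM5, fixed in the interferon list but known for its expression in osteoblasts, stood at 210 against 47.8 RPKM. In all, 267 genes were at least 2-fold higher and 356 lower among 12626.

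Of 15 measured tendon and fibroblast genes in Q317K, 4 were at least 2-fold higher and 2 lower, with a median log2 ratio of 0.41 at percentile 94.97, inside the central 95% of random lists. COL3A1, a fibrillar collagen of soft connective tissue, stood at 784 against 121 RPKM, 6.47-fold higher (6.33 to 6.61), and the proteoglycans ASPN (123 against 34.4) and LUM (200 against 72.8) were higher while FMOD (77.0 against 312) was lower. The 8 largest positive ratios were those of COL3A1, NELL2 (103 against 7.43), the peptide hormone CCK (187 against 16.7), the carboxypeptidase CPZ (56.9 against 6.68), N-cadherin CDH2 (173 against 25.02), tissue factor F3 (41.7 against 5.57), F2RL2 (31.3 against 3.97) and PPFIBP2 (41.4 against 5.82). Beside ACAN, MATN1, COMP and COL2A1, the most negative were EPYC (6.23 against 77.1), NRIP3 (8.36 against 81.2), HEPACAM (17.8 against 159) and PAPSS2 (34.1 against 296), which makes the sulfate donor of proteoglycans. Of 14 measured WNT genes 4 were higher, with LGR5 at 25.04 against 6.52 RPKM and RSPO3 at 12.4 against 3.38, and 2 were lower, with SFRP2 at 34.8 against 98.6. The hedgehog-binding protein HHIP stood at 57.5 against 14.5, and the receptor FGFR3 at 36.5 against 194. Skeletal muscle markers, measured as a possible other cell type, had a median log2 ratio of 0.12 at percentile 95.7, with ACTC1 at 73.5 against 35.8 RPKM. Epithelial markers lay outside the central 95%, with a median of −0.54 at percentile 0.42, though none of the 8 measured changed 2-fold.

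Q317R cultures kept most of their cartilage transcripts but had low levels of bone-type genes. Only 3 of 16 measured cartilage genes were at least 2-fold lower, MATN3 (8.29 against 29.7), EPYC (23.2 against 77.1) and COMP (268 against 649), while the matrilin MATN4 stood at 2489 against 531 RPKM, 4.69-fold higher (4.61 to 4.77). The list median was −0.53 on the log2 scale, still below all 10000 random lists. In the hypertrophic cartilage and bone list 5 of 10 genes were lower and none higher; SPP1 stood at 93.9 against 573 RPKM, 6.10-fold lower (5.80 to 6.42), IBSP at 10.5 against 34.4, PANX3 at 22.1 against 66.0 and ALPL at 55.3 against 151. In all, 237 genes were at least 2-fold higher and 256 lower among 12753.

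The largest positive ratios in Q317R were those of NELL2, at 143 against 7.43 RPKM or 19.2-fold (17.2 to 21.4), SERPINI1 (74.4 against 5.27), the muscle growth inhibitor MSTN (14.8 against 0.95), the nucleoside transporter SLC28A2 (84.0 against 9.97), SPOCK3 (45.6 against 6.15), MFAP3L (55.7 against 8.86), LRRC3B (24.7 against 3.61) and BMP4 (76.2 against 14.1). The most negative were C1QTNF3 (24.3 against 237), the metalloproteinase inhibitor TIMP4 (7.25 against 64.0), NRIP3 (11.1 against 81.2), SPP1, KCTD12 (17.7 against 95.8), PRELP (114 against 584), MAB21L2 (21.3 against 108) and the small heat shock protein HSP25 (68.1 against 335). Tendon and fibroblast genes had a median log2 ratio of −0.38 at percentile 0.49, with 6 of 15 lower, among them THBS2 (19.9 against 81.0), DCN (71.9 against 266) and COL6A1 (138 against 446). Low medians also occurred among markers of other cell types. Skeletal muscle markers had a median of −0.47 at percentile 0.01 and epithelial markers −0.29 at percentile 2.05, though none of either list changed 2-fold. Endothelial, neuronal and adipocyte markers lay at percentiles 19.9, 10.5 and 4.29. CYP26B1 stood at 91.1 against 24.5 RPKM and ALDH1A2, an enzyme that makes retinoic acid, at 4.48 against 1.55.

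In the PITX1 cultures cartilage and hypertrophic genes were lower and a pair of globin genes stood far above every other library. Of 16 measured cartilage genes 12 were at least 2-fold lower, with a median log2 ratio of −1.47, below all 10000 random lists; MATN1 was 13.9-fold lower (12.6 to 15.3), MATN3 9.85-fold lower (7.84 to 12.5), COMP 5.24-fold lower (5.09 to 5.39) and COL2A1 4.71-fold lower (4.65 to 4.76). COL10A1 (19.7 against 67.7), IHH (11.9 against 33.8), ALPL (62.6 against 151) and IBSP were lower in the hypertrophic cartilage and bone list and none of its genes was 2-fold higher. The embryonic globin HBE stood at 747 against 6.77 RPKM, 110-fold higher (84.7 to 147), and the related HBB at 40.2 against 2.15; HBB resembles HBE in sequence, so its level is uncertain. In all, 245 genes were at least 2-fold higher and 349 lower among 12614.

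Of 12 measured retinoic acid genes in the PITX1 library 3 were at least 2-fold higher and 2 lower, with a median log2 ratio of −0.23 at percentile 9.31, inside the central 95% of random lists. The retinol-binding protein receptor STRA6 stood at 52.0 against 11.6 RPKM, 4.49-fold higher (3.98 to 5.07), CYP26B1 at 97.49 against 24.5 and ALDH1A2 at 6.30 against 1.55, while CRABP1, which binds retinoic acid, was at 7.49 against 23.2. Of 29 measured limb patterning genes 10 were lower, among them FGFR3 (35.4 against 194), MAB21L2 (25.2 against 108) and SPRY2 (21.4 against 51.7), and none was higher. TBX4, the hindlimb T-box factor, stood at 11.6 against 29.2 RPKM, and the forelimb factor TBX5 at 16.2 against 49.4. After HBE and HBB, the largest positive ratios were those of OLFM1 (60.05 against 7.90), the adhesion molecule SELE (33.8 against 4.94), FHL2 (38.3 against 5.98), RXFP2 (63.3 against 10.5), FABP7 (79.2 against 14.4) and the integrin ITGA8 (169 against 31.8). Among the most negative, beside MATN1 and MATN3, were C1QTNF3 (24.4 against 237), HSP25 (40.7 against 335), the glycoprotein hormone STC2 (41.8 against 337), the serine synthesis enzyme PSPH (24.4 against 155), CHRDL2 (9.88 against 62.5) and SDC3 (79.7 against 463). Elastin, ELN, stood at 817 against 302 RPKM.

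**Figure D2:**
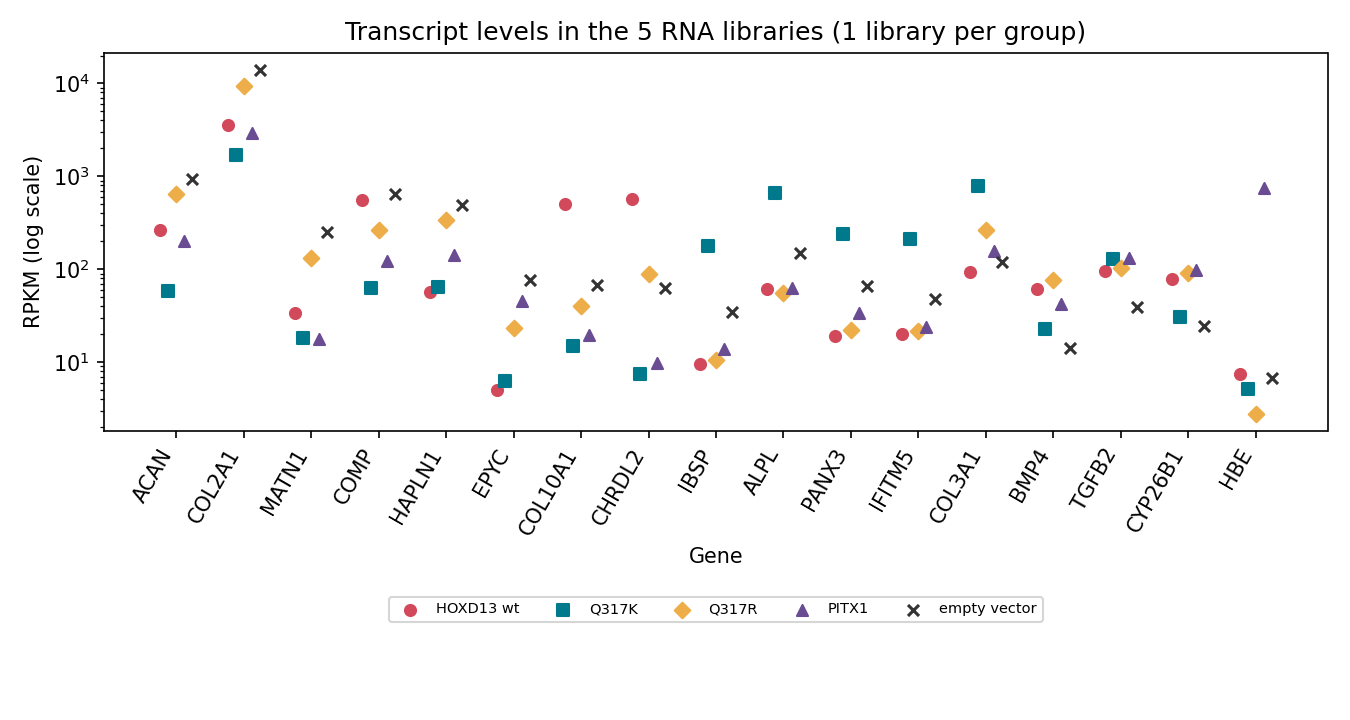
Each point is the RPKM (log axis) of 1 gene in 1 RNA library, with colours and symbols marking the 5 libraries. COL10A1 and CHRDL2 are highest in HOXD13 wt (502 and 576), IBSP, ALPL, PANX3, IFITM5 and COL3A1 in Q317K, and HBE in PITX1 (747).

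Several gene groups lay on the same side of the empty vector in all 4 factor libraries. Among them was the cartilage list, with medians of −1.54, −2.88, −0.53 and −1.47 in HOXD13 wt, Q317K, Q317R and PITX1, so its lower levels rest on the same single empty vector library. Of 26 measured HOX genes besides HOXD13, 24 had negative log2 ratios in HOXD13 wt, 25 in Q317K, 24 in Q317R and 25 in PITX1, with medians of −0.48, −0.53, −0.41 and −0.48, each below all 10000 random lists. HOX paralogs can share reads, which leaves single members uncertain. Of 32 genes of other organs, 14 were also highest in the empty vector library. HOXD11 stood at 24.6 RPKM in the empty vector and between 8.48 and 9.97 in the others. TBX5 was 49.4 RPKM in the empty vector and 17.6, 10.8, 19.3 and 16.2 in HOXD13 wt, Q317K, Q317R and PITX1, and FGFR3 was 194 against 73.8, 36.5, 76.5 and 35.4. TGFB2 was higher in each, from 95.8 to 133 against 39.7 RPKM. The 17 measured proliferation genes had medians of 0.50, 0.44, 0.58 and 0.25 at percentiles of 100, 99.98, 100 and 99.3, though only ANLN and CDK1, both in Q317K, reached 2-fold. In total 55 genes were at least 2-fold lower in all 4 factor libraries and 8 were higher. The comparisons share 1 empty vector library, and with unchanged groups simulated against it the correlation of log2 ratios was already 0.48 to 0.52. The observed values were 0.68 for HOXD13 wt with Q317R, 0.67 for Q317K with PITX1, 0.53 for Q317K with Q317R, 0.47 for HOXD13 wt with Q317K, 0.43 for Q317R with PITX1 and 0.42 for HOXD13 wt with PITX1. In the same order the simulated correlations were 0.51, 0.49, 0.50, 0.48, 0.52 and 0.50, so the last pairs, with 0.47, 0.43 and 0.42, lay below theirs. The covariances were 0.158, 0.173, 0.127, 0.124, 0.0968 and 0.106, against 0.00961 to 0.00969 in the simulations. These simulations hold counting noise only. Variation between cultures, which the single empty vector library brings into every pair, is not in them, so higher covariances do not show a shared response. Q317K and PITX1 shared 204 genes lower than the empty vector and 68 higher, where independent lists would share 9.98 and 4.17, and HOXD13 wt and Q317R shared 144 and 81 where independent lists would share 6.81 and 4.67. The other pairs shared between 95 and 139 lower genes, with 7.17 to 9.54 for independent lists. Higher genes were shared by Q317K and Q317R at 64 (4.24 for independent lists), by HOXD13 wt and Q317K at 35 (4.88), by Q317R and PITX1 at 25 (3.69) and by HOXD13 wt and PITX1 at 23 (4.62). Lists called against the same library are not independent, so part or all of each excess may come from the shared control.

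Compared directly, without the empty vector, Q317K and HOXD13 wt differed in cartilage, hypertrophic, bone and connective tissue genes. Of 16 cartilage genes 8 were at least 2-fold lower in Q317K and none higher, with a median of −0.95 below all 10000 random lists; COMP was 8.81-fold lower (8.45 to 9.18) and CHAD, a cartilage leucine-rich protein, 5.10-fold lower (4.57 to 5.70). CHRDL2 was 77.1-fold lower in Q317K (66.2 to 90.4) and COL10A1 33.6-fold lower (30.5 to 37.1), while IBSP was 18.6-fold higher (15.5 to 22.4), PANX3 12.4-fold, ALPL 10.8-fold and IFITM5 10.6-fold. Of 15 tendon and fibroblast genes 8 were higher, with COL3A1 at 784 against 92.4 RPKM and the matrix glycoprotein TNC at 325 against 80.0, and 2 were lower, the proteoglycans FMOD (77.0 against 439) and OGN (13.3 against 52.7), and the list median of 1.05 lay above all 10000 random lists. CCK (187 against 9.26), CDH2 (173 against 12.7), CPZ (56.9 against 4.996) and TNFSF4 (50.3 against 4.54) were the other genes of largest positive ratio, and FGFBP2 (2.61 against 59.4), ANXA8 (2.90 against 52.8), ST6GAL2 (3.36 against 59.1), PODNL1 (13.0 against 144), STC2 (46.5 against 484) and CPE (24.1 against 236) the other most negative. Of 15 muscle markers 4 were higher, among them ACTC1 (73.5 against 22.0) and TNNI1 (35.9 against 11.9), and their median of 0.50 lay above all 10000 random lists. NOG stood at 12.3 against 92.1 RPKM. In all, 373 genes were higher in Q317K and 401 lower, among 12412.

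Q317R differed from HOXD13 wt at fewer genes, 184 higher and 206 lower among 12555. Most cartilage genes were higher in Q317R: 10 of 16 by at least 2-fold, with a median log2 ratio of 1.17, above all 10000 random lists. The other way went COMP, at least 2-fold lower at 268 against 560 RPKM. HAPLN1 stood at 338 against 56.5 RPKM, 5.99-fold higher (5.68 to 6.31), COL9A1 at 700.3 against 168 and MATN1 at 132 against 34.1. Of 15 tendon and fibroblast genes 5 were lower, among them DCN (71.9 against 286) and OGN (13.5 against 52.7), and 2 higher, with a median of −0.29 at percentile 0.02. The 4 measured adipocyte markers, of another cell type, all had positive log2 ratios in Q317R, with a median of 0.66 at percentile 99.89. Only LPL, at 64.5 against 25.7 RPKM, reached 2-fold. COL10A1 (40.3 against 502), CHGB (25.1 against 359), CHRDL2 (89.7 against 576), the cystatin CYT (264 against 2403), RGS5 (7.25 against 69.5), ANXA8 (4.92 against 52.8), the metalloproteinase MMP3 (2.17 against 23.2) and ST6GAL2 (10.0 against 59.1) were the most negative. Beside HAPLN1, the most positive were MFAP3L (55.7 against 4.66), the nuclear receptor NR4A3 (154 against 19.1), the growth factor GDF10 (68.0 against 8.77), the integrin ITGB4 (78.8 against 10.5), CPM (39.5 against 5.27), SUSD5 (175 against 26.3) and CPZ (35.8 against 4.996). The 15 measured interferon response genes were all higher in Q317R than in HOXD13 wt, with a median of 0.55 and 3 past 2-fold, IRF1, USP18 and ZNFX1.

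Q317K and PITX1, whose homeodomains share lysine at the matching position, differed by 234 genes higher and 203 lower in Q317K among 12147. Bone-type genes stood apart: IBSP was 12.8-fold higher in Q317K (11.1 to 14.9), ALPL 10.7-fold, IFITM5 8.87-fold and PANX3 7.07-fold. The hypertrophic cartilage and bone list median of 0.96 lay above all 10000 random lists. ALPL entered that list after the largest ratios had been seen, so this placement is not independent of the data. Skeletal muscle markers, of another cell type, had a median of 0.37, also above all random lists, with MYH3 at 8.22 against 2.83 RPKM and TNNI1 at 35.9 against 14.97. Of 32 genes of other organs, 8 in Q317K and 7 in PITX1 also reached 5 RPKM. A low level such as that of MYH3 therefore does not by itself show muscle cells. TNNI1 in Q317K lay above the highest of the 32 there, at 17.5 RPKM, so muscle cells are not excluded. Of 16 cartilage genes 6 were lower in Q317K and none higher, with a median of −0.60 below all random lists. CCK (187 against 10.1), the crosslinking enzyme TGM2 (330 against 22.1), ANGPTL7 (162 against 15.8), HHIP (57.5 against 6.38) and EGFL7 (128 against 16.9) were the other most positive. HBE (5.08 against 747), HBB (2.21 against 40.2), RXFP2 (6.36 against 63.3), WFIKKN1 (11.1 against 86.4), the cardiac myosin MYSC (1.505 against 16.9), KAZALD1 (19.04 against 133), the cochlear keratin K2CO (5.49 against 42.4) and EPYC (6.23 against 45.2) were the most negative. STRA6 stood at 7.82 against 52.0 RPKM and CYP26B1 at 30.3 against 97.49.

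Over all 10 pairs of RNA libraries, the fewest genes at least 2-fold apart were found between HOXD13 wt and Q317R, with 390, and between Q317K and PITX1, with 437. The most were found between HOXD13 wt and PITX1, with 793, and between HOXD13 wt and Q317K, with 774. On libraries that share no control, the change from HOXD13 wt to Q317K correlated across 13002 genes with the change from the empty vector to PITX1, at Pearson r = 0.246 (0.218 to 0.272 over 1000 resamplings of genes) and Spearman rho = 0.193. For the change from HOXD13 wt to Q317R, r was −0.048 (−0.077 to −0.020) and rho −0.083 across 13048 genes. Genes are not independent replicates, and these intervals leave out the variation between cultures.

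**Figure D3:**
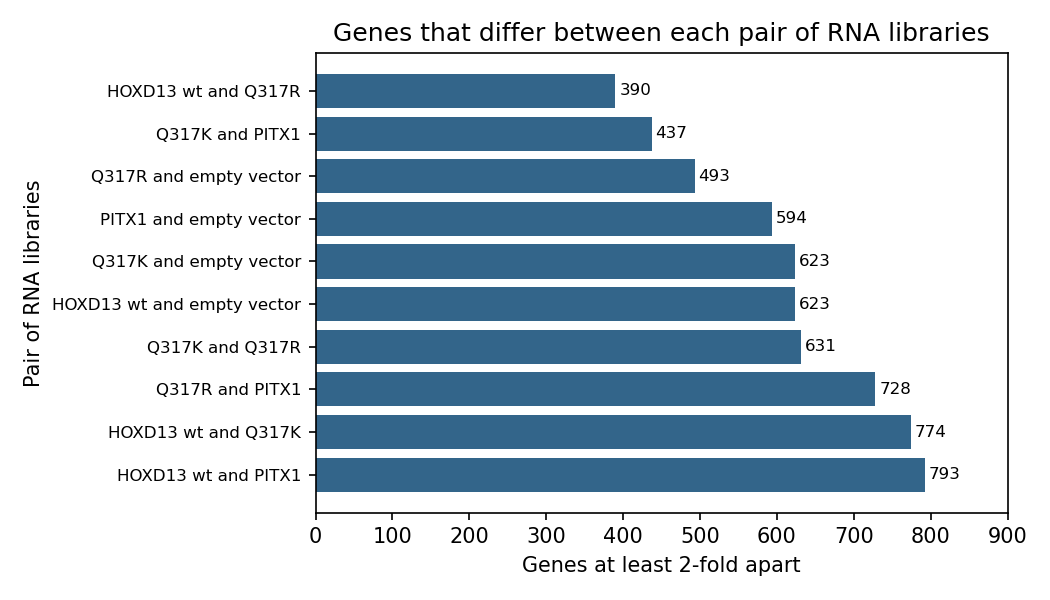
Bars show the number of genes at least 2-fold apart, in either direction, between each pair of the 5 RNA libraries, counted among genes with an RPKM of at least 5 in 1 or both. HOXD13 wt with Q317R (390) and Q317K with PITX1 (437) are the closest pairs, and HOXD13 wt with PITX1 (793) the most distant.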

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

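The tests on globins, the count of genes changed with Q317K alone, the comparison with genes of other organs and the rule that picked the genes below were chosen after the values were seen; the others were set beforehand, although COL10A1, CHRDL2 and bone genes had been seen to go opposite ways when the bound on opposite genes was written. None of these differences was tested, since each group had 1 library. Among named genes, 25 were at least 2-fold above the empty vector with one HOXD13 form and at least 2-fold below it with another. The 8 with the widest gap in log2 ratio were CHRDL2 (6.09), COL10A1 (4.98), FGFBP2 (4.06) and ANXA8 (3.79), higher with HOXD13 wt and lower with Q317K; IBSP (4.08), PANX3 (3.56) and IFITM5 (3.34), higher with Q317K and lower with HOXD13 wt; and ALPL (3.57), higher with Q317K and lower with Q317R.

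Q317K RNA resembled PITX1 RNA more than wild-type RNA did (r = 0.246 on libraries without a shared control). The bound set beforehand was an r below 0.1 if cartilage, bone and tendon genes alone carried this. Without those 3 lists and all genes 4-fold apart, 223 genes in all, r was 0.215 (0.192 to 0.238). This argues against the removed genes alone carrying the correlation. Unlisted genes of these tissues and smaller changes stayed in, so the value does not decide whether a wider change in cartilage and bone carries it. Several values go against a weaker dose of HOXD13 wt, which the lower HOXD13 row in Q317K could reflect. Cartilage genes lay further below the empty vector in Q317K (median −2.88) than in HOXD13 wt (−1.54). Also, 23 genes changed 2-fold in opposite directions (18 to 27 over other settings), against 20 set beforehand as excluding a weaker dose. After that outcome the rule for reading the count was altered more than 1 time and a second count was added, 236 genes 2-fold changed in Q317K and within a log2 ratio of 0.5 of the empty vector in HOXD13 wt (simulated mean 1.10). The simulations of a weaker dose put every level midway between HOXD13 wt and the empty vector. Their means, 0 opposite genes and 1.10 in the second count, therefore follow from the construction. They also hold counting noise only, and each group is 1 culture. A weaker dose plus variation between cultures therefore cannot be told apart from another activity of Q317K. Nor was a binding preference shared with PITX1 tested on RNA.

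HBE and HBB were high in the PITX1 library alone. Red blood cells in that culture would bring alpha globins too, yet HBAA (2.76 RPKM) and HBAD (2.28) together came to 0.674% of HBE and were no higher than in the other libraries, which argues against them. For HBB, reads shared with its paralog HBE cannot be told apart from its own transcripts: in the other libraries, where HBE was low, the highest HBB level was 1.70 times their median, so no library separates the genes. An effect of PITX1 on the beta-globin genes, or a peculiarity of this culture, may remain.

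The 55 genes 2-fold lower in all 4 factor libraries than in the empty vector may reflect that library standing apart or a response shared by the factors, which cannot be told apart. A test set beforehand took the first explanation as fitting if another library as the reference gave at least 1 gene for every 2 of these 55. HOXD13 wt as the reference gave 86 genes lower in all the other 4 libraries, PITX1 79, Q317K 62 and Q317R 29. That bound was met. But each of these libraries carries a factor of its own, and genes raised by it alone enter its count. A condition for this, absent from the bound as first set, was added to the rule, so the test does not decide. Of 26 HOX genes, 22 were highest in the empty vector library, against 2 in HOXD13 wt, 1 in Q317K, 1 in Q317R and 0 in PITX1, as were 14 of 32 genes of other organs. The median log2 ratios of the latter were −0.07, −0.29, −0.02 and −0.16 in HOXD13 wt, Q317K, Q317R and PITX1. Those of the HOX genes were −0.48, −0.53, −0.41 and −0.48. Genes of other organs lie near the floor, where the log2 scale understates ratios. Their median RPKM was 3.17 in HOXD13 wt and 3.14 in Q317R, near the 3.20 of the empty vector. It was lower in Q317K (2.59) and PITX1 (2.82). These values go both ways, so a background difference of the empty vector library stays open. The same limit holds for the cartilage list, below all random lists in each factor library, and a second empty vector library would be needed to separate the explanations.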

How the results depend on the processing

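The alternatives of one threshold for all peak lists, of the strongest 5000 peaks against full lists, of RPKM 20 and of another transcript per gene were chosen after seeing the data, as were those for comparisons between factors and for the genes changed in opposite directions. The 14 counts of 2-fold genes stayed within 1.5 times their main value under all 5 alternatives. The 8 most positive and 8 most negative named genes of each comparison kept their sign with another pseudocount, centred ratios or another transcript. Genes named through a list or outside the rule were not re-run one by one. The 72 list medians kept their sign except that of the endothelial list in HOXD13 wt, which was −0.01 and became 0.02 with centred ratios. Overlap shares moved with every rule except −log10 p of at least 10, which removed no peak and so tests nothing; with fewer or narrower targets a lower share follows from the construction, and for the other shifts the cause was not tested. In the order HOXD13 wt, Q317K and Q317R with PITX1, then Q317K and Q317R with HOXD13 wt, the shares were 1.11%, 6.62%, 2.94%, 5.93% and 27.5% for summits within 100 bp, 2.92%, 10.7%, 6.47%, 9.36% and 31.1% for overlap of at least 50% of both peaks, 1.26%, 4.16%, 2.78%, 3.76% and 16.1% for the strongest 5000 peaks of each list, 5.73%, 14.5%, 10.8%, 15.5% and 42.9% for one −log10 p threshold of 52.1, and 6.48%, 18%, 12.8%, 18.9% and 49.6% for the strongest 5000 peaks against full lists. In all of these Q317K exceeded Q317R and HOXD13 wt in overlap with PITX1, and Q317R exceeded Q317K in overlap with HOXD13 wt; Q317K overlapped HOXD13 wt more than PITX1 under the last pair of settings and less under the others. The correlation of the Q317K change with the PITX1 change was 0.193 as Spearman rho and 0.281 at an RPKM of at least 20, and that of the Q317R change −0.083 as Spearman rho. The 28 alternatives for motifs and genes near peaks were not run. No paired analysis was possible because each group had 1 library or list. Depth limits genes near 5 RPKM most, where counting intervals are wide.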

Other observations

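The grouping of chromosomes and the list of genes of other organs were chosen after the data were seen. PITX1 peaks were spread over the chromosomes differently from those of the HOXD13 forms. On the small chromosomes 10 to 28 lay 23.6% (23.1 to 23.97) of PITX1 peaks, against 11.9% (11.6 to 12.3) for HOXD13 wt, 13.9% (13.4 to 14.3) for Q317K and 12.2% (11.8 to 12.7) for Q317R. In density this was 48.5 PITX1 peaks per Mb there and 37.3 per Mb on chromosomes 1 to 5, while HOXD13 wt had 20.6 and 39.1. Q317K, with 17.5 and 27.5, and Q317R, with 13.2 and 24.3, kept the order of HOXD13 wt. On chromosome Z the shares lay between 4.13% in Q317R and 4.62% in Q317K.

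Other gene groups are given as median log2 ratios to the empty vector. Limb patterning genes had negative medians in HOXD13 wt, Q317K, Q317R and PITX1, at −0.36, −0.38, −0.32 and −0.53, with 4, 6, 3 and 10 of 29 at least 2-fold lower. In Q317K 4 of them were also at least 2-fold higher, and in the other factor libraries none was. Limb identity genes had medians of −0.41, −0.54, −0.22 and −0.36, and retinoic acid genes −0.29, −0.37, −0.22 and −0.23. BMP and TGF-beta genes had medians of 0.06, −0.13, 0.24 and −0.31, WNT genes 0.44, 0.07, −0.01 and −0.13, and tendon genes −0.30, 0.41, −0.38 and 0.22. Bone list medians were −0.80, 0.40, −0.87 and −0.93, and the stress list, −0.03, −0.19, −0.13 and −0.30, had ATF3 lower in each factor library (38.8, 22.1, 36.7 and 22.5 against 104 RPKM). Interferon genes had medians of −0.49, −0.33, 0.07 and −0.40, with CMPK2 at least 2-fold lower in HOXD13 wt, Q317K and PITX1. Among markers of other cell types, muscle medians were −0.42, 0.12, −0.47 and −0.34, epithelial −0.28, −0.54, −0.29 and −0.40, endothelial −0.01, −0.33, −0.16 and −0.32, neuronal −0.15, −0.23, −0.21 and −0.21, and adipocyte −0.61, −0.25, −0.34 and −0.48. Single markers stood out, with KRT19 at 42.8 against 9.70 RPKM and FLT1 at 10.1 against 2.73 in PITX1, EGFL7 at 128 against 30.9 and STMN2 at 10.4 against 2.29 in Q317K, and ERG at 121 against 54.3 in HOXD13 wt. In the blood list 1 gene was measured, HBE, with log2 ratios of 0.12, −0.35, −1.03 and 6.59.

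Transcripts of other organs were listed at a low level in every library. Of 32 genes restricted to organs such as oviduct, lens, liver and pituitary, the median was 3.17 RPKM in HOXD13 wt, 2.59 in Q317K, 3.14 in Q317R, 2.82 in PITX1 and 3.20 in the empty vector, and 9, 8, 7, 7 and 7 of them reached 5 RPKM. Of the 32, 14 were highest in the empty vector, 8 in HOXD13 wt, 1 in Q317K, 6 in Q317R and 3 in PITX1. Ovalbumin, OVAL, was at 8.37 RPKM in HOXD13 wt, with 234 reads, against 1.40 to 3.02 in the other libraries. No row of the table was at 0 in any library. The row of highest RPKM in all 5 libraries, LOC768852, stood at 44704 in HOXD13 wt and between 15599 and 22055 in the others.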
